A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

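RNA bound to Gbp2, Hrb1 and Npl3, each carrying a myc tag per the labels, was compared with lysate RNA of the same culture on 6 spotted yeast arrays, 2 per protein. Per the labels' protocols, the lysates came from cells grown in selective medium, the tagged proteins were immunoprecipitated in independent experiments with c-myc antibody beads or GFP-Trap beads (which of them per array is not stated), and RNA was taken from the eluate and from a portion of lysate set aside beforehand. The protocols describe amplification of RNA, reverse transcription and dye coupling. On every array the lysate carried Cy3 and the eluate Cy5, so the orientation of the dyes was never exchanged. No immunoprecipitate from an untagged strain was among the 6 arrays. The titles of the arrays spell Hrb1 as Grb1. The series design and the protocol name Hrb1, and the arrays were grouped under that name.

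The scanner files hold, per the file headers, spot brightness as raw intensity with the local background of each channel. The arrays Gbp2 replicate 1, Gbp2 replicate 2, Hrb1 replicate 1 and Npl3 replicate 1 were read with ScanArray Express 4.0.0.4 on separate days, and Hrb1 replicate 2 and Npl3 replicate 2 with Agilent Feature Extraction 10.5.1.1 on 1 day. The deposited value table holds log2 ratios of the channels, made by the authors with limma per the submitters' processing notes, with no version given. Its spot numbers did not match the scanner values (absolute rank correlation at most 0.0359), whereas the alphabetical order of the open reading frame names gave rank correlations between -0.898 and -0.181, so the table was read as lysate over eluate. On Hrb1 replicate 2 and Npl3 replicate 2 this rested on weak evidence, since Pearson r by the same order was 0.03 and 0.04. Its scale and centring are not stated, and its medians were 0.29 on Hrb1 replicate 2 and 0.19 on Npl3 replicate 2. The table was therefore used only as an alternative, with its sign turned, and 0 of its columns were left unused.

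Each array carries 13056 spots, among them 6293 open reading frame names on adjacent duplicate spots and control spots of buffer and Arabidopsis DNA. Names were matched to the reference table of current genes, 5716 by locus tag and 5773 when synonyms were added, and 520 stayed unmatched under their array names. Of the entries, 5734 were nuclear protein-coding genes. Brightness was corrected for background with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, ratios of eluate over lysate were normalised within each array by loess, and the spots of each name were averaged. Control spots and spots that the scanner software marked bad were left out, spots it marked not found were kept, and 4 genes lacked a value on 1 or more arrays. No filter on dim spots was applied. Brightness above background meant a foreground over the background median plus 2 background SDs. Figures were drawn with Python 3.11.15.

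A linear model with 1 coefficient per protein was fitted to the log2 ratios with limma, with empirical Bayes moderation (prior degrees of freedom 4.78, residual degrees of freedom 3), and p-values were adjusted by Benjamini and Hochberg over all genes of a comparison at a threshold of 0.05. The 6 comparisons were each protein's eluate against its lysate, and the differences Gbp2 against Npl3, Hrb1 against Npl3 and Gbp2 against Hrb1. Tests were two-sided. A difference between proteins removes a gene's dye effect only where it has the same size on all arrays, whereas a ratio against 0 still contains it. The number of arrays limits the precision. An exact permutation of 2 arrays against 2 cannot give a p under 0.333.

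Gene lists with at least 5 measured members were tested with camera of limma at a preset correlation between genes of 0.01, and again with a correlation estimated from the arrays. The second test also rests on the 3 residual degrees of freedom of the arrays, which by itself raises its p-values. In Hrb1 against Npl3 the estimated correlation of the SR-like list was 0.0163. Its unadjusted camera p still rose from 0.00958 to 0.0959. Not passing the second test therefore does not show that correlation between genes made a call. The 20 lists and 6 comparisons made 120 tests, adjusted together. The lists were intron-containing genes, these split into genes with and without ribosomal protein products, intronless ribosomal protein genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, mitochondrial genome transcripts, histones, glycolysis and fermentation, ribosome biogenesis, translation factors, the proteasome, chaperones and heat shock, cell wall and secreted proteins, plasma membrane transporters and the proton pump, the nuclear-encoded respiratory chain and ATP synthase, amino acid biosynthesis, ergosterol biosynthesis, SR-like, mRNA export and nuclear surveillance proteins, and spliceosome proteins. A list's shift is the median log2 ratio of its members minus that of its comparison genes on each array, averaged over the arrays of a protein. Intron-containing genes were compared with intronless nuclear protein-coding genes, those with ribosomal protein products with the intronless ribosomal protein genes, and other lists with all other entries. The mean of a list's shifts over the 6 arrays was also tested against 0 with an exact test over the 64 sign flips, whose smallest possible p is 0.0313.

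The reference table holds no exons, so the intron-containing list was written from general knowledge of the yeast genome. All 217 of its measured members had a genomic span in the table, which was not a multiple of 3 nucleotides for 58.5% of them, against 1.02% of the 5517 other nuclear protein-coding genes. Lists of snoRNAs and snRNAs and of other nuclear noncoding RNAs had 0 measured members. Retrotransposon reading frames were not tested as a list, because the spots of a repeated family share sequence.

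The tests, lists, alternatives and naming rule were chosen before the data were examined, apart from the additions named here and in the closing part. By the naming rule, genes past the threshold would be named first. None passed, so the 3 genes at each end of a comparison by moderated statistic are given as values only. The rule adds the 2 highest members and the lowest member of each list, and GBP2, HRB1, NPL3, ACT1, YRA1, DBP2, RPS6A, RPL23A, TDH1, ASC1, ECM33, RPS11B and PMA1. Of the genes it takes, the text gives those that bear on the groups described.

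The pipeline was tested on simulated data with 50 changed genes per protein and size of change among 6289 genes. With a change of 1 on the log2 scale, 28% of changed genes were recovered for Gbp2, 18% for Hrb1 and 16% for Npl3. With a change of 2, these shares were 96%, 94% and 94%. Among unchanged genes, 11, 7 and 8 were called. The shares of recovered genes hold for the simulated data only. In the measured data, YGR115C at 2.22 and YGR114C at 2.90 for Gbp2 did not pass (limma adjusted p = 0.213). The shares therefore cannot show that changes of 2 were absent from the arrays. A simulated shift of 0.50 in the cell wall list was called in each protein, with 0 other lists called. The simulated genes varied independently, whereas the correlation estimated from the arrays reached 0.737 for glycolysis and 0.470 for ribosome biogenesis. The simulation therefore cannot show whether such correlation gives false list calls at the preset value.

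Alternatives were median centring without loess, no background correction, normexp with an offset of 0, the deposited table, genes above background in at least 1 channel of every array, arrays scaled to the same spread, replicate number and scanner format as blocks, leaving out each array, a 2-fold minimum, array weights, and for the intron-containing list intronless genes matched on lysate brightness, the mean, and ribosomal protein genes left out. Added after the data were seen were the removal of Gbp2 replicate 1 and Npl3 replicate 1 together, an intron-containing list restricted to members with a span not divisible by 3, and the sign-flip test. With 1 array of a protein left out, the remaining array was assumed to vary like the other groups. Both Gbp2 arrays were read with ScanArray, so scanner format as a block adjusts Gbp2 by the gap between scanners in Hrb1 and Npl3. That gap is also replicate 1 against replicate 2 and includes Npl3 replicate 1, where few spots were found. The Gbp2 values of this setting are therefore extrapolations.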

Results

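The series asks which yeast mRNAs are bound by the shuttling SR-proteins Gbp2 and Hrb1, which its title connects with the quality control of spliced mRNAs, and by the SR-like protein Npl3. RNA that co-purified with each tagged protein was measured against lysate RNA of the same cells on 2 arrays per protein. All values are log2 ratios of eluate over lysate, normalised by loess unless stated otherwise. A positive value means a higher ratio than that of genes of like brightness on the array, not a share of the RNA. A shift shared by most genes of a given brightness is removed by loess. No untagged immunoprecipitate was among the arrays, so RNA in the eluate cannot be equated with bound RNA.

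The arrays differed in what they detected. Spots were found by the scanner software at 12628 of 13056 positions on Gbp2 replicate 1, 12625 on Gbp2 replicate 2, 11687 on Hrb1 replicate 1, 12958 on Hrb1 replicate 2, 1498 on Npl3 replicate 1 and 12898 on Npl3 replicate 2. On Npl3 replicate 1 the median lysate spot had a brightness of 1313.5 over a local background of 1287, and 10.3% of genes stood above background in the lysate and 9.14% in the eluate. On the other 5 arrays these shares ran from 90.9% to 98.2% in the lysate and from 88.6% to 97.6% in the eluate. The lysate signals of Gbp2 replicate 1 correlated with those of the other arrays at a median Spearman rho of 0.351 and those of Npl3 replicate 1 at 0.209, against 0.587 to 0.661 for each other array. Of the 217 genes taken by the naming rule, 23 were above background in both channels on Npl3 replicate 1, against 200 to 205 on each other array. The 2 arrays of a protein gave such genes opposite signs in 97 cases for Gbp2, 73 for Hrb1 and 91 for Npl3. The number of arrays limits the precision of every value.

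Cell wall and secreted protein mRNAs were lower in the eluate than in the lysate on 6 of 6 arrays. So were 2 other lists, amino acid biosynthesis and the intron-containing genes without ribosomal protein products, by smaller mean shifts (-0.15 and -0.04 over the 6 arrays). The cell wall list holds the mannoproteins and glucan-modifying enzymes of the cell surface. Its mean shift was -0.53 ± 0.28 (SD, n = 6 arrays; exact sign-flip p = 0.0313, the smallest possible, and 0.208 adjusted over 20 lists). On Npl3 replicate 1 the list lay, without loess, at percentile 39.21 of lists matched on brightness. Brightness may therefore account for the value there. Without an exchange of dyes or an untagged control, the shift cannot be read as a property of binding. The 3 bound proteins are described in turn, then the differences between them.

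**Figure D1:**
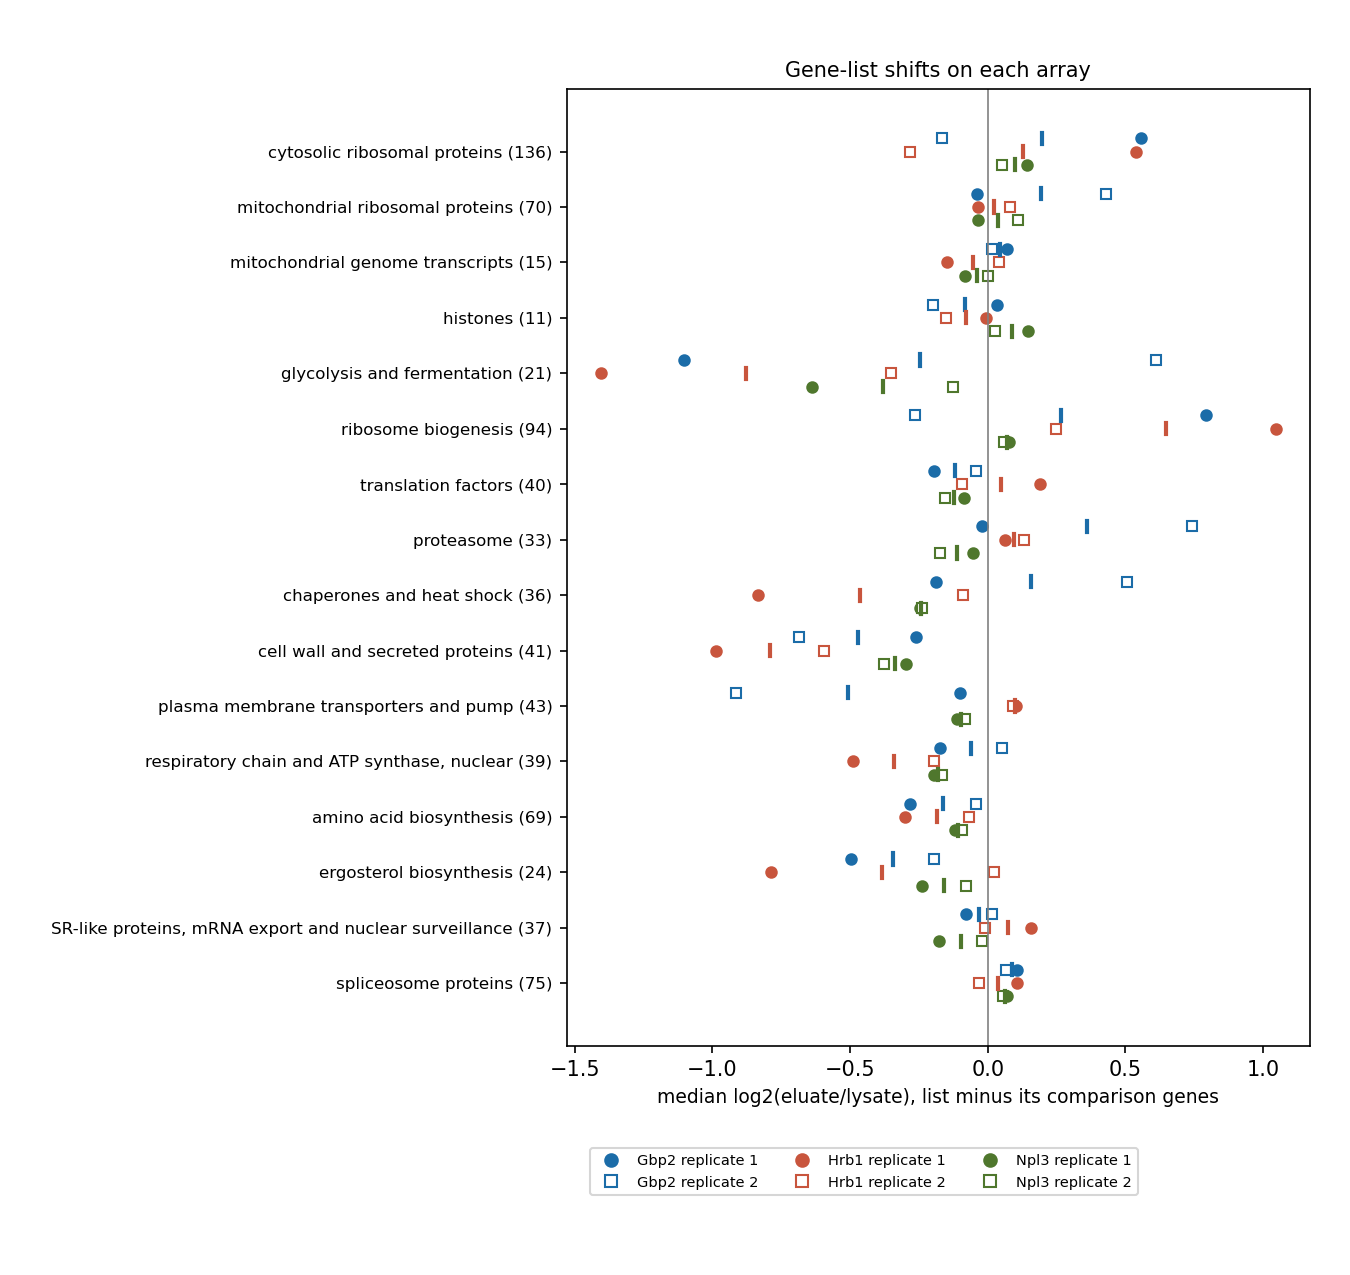
Shift of each gene list on each array, as the median log2(eluate/lysate) of the list minus that of its comparison genes on the horizontal axis. Colours are the proteins, filled circles replicate 1, open squares replicate 2 and short bars their mean. The cell wall list lies between -0.99 and -0.26 on the 6 arrays, whereas glycolysis spans -1.41 to 0.61.

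For Gbp2, camera at the preset correlation placed transporter and cell wall mRNAs lower and proteasome mRNAs higher. The transporter and proteasome calls ended without Gbp2 replicate 2. None of these lists passed with an estimated correlation (adjusted p = 0.967 with an estimated correlation for each). That test has 3 residual degrees of freedom, so not passing it, here or below, says little about correlation between genes. Plasma membrane transporter mRNAs were lower by a shift of -0.51 ± 0.58 (SD, n = 2), with 37 of 43 members below 0, and cell wall mRNAs by -0.47 ± 0.30, with 33 of 41 below 0. The mRNA of PMA1 (YGL008C), the proton pump of the plasma membrane, had the lowest value among transporters, at -2.38 ± 0.33 (SE; -2.88 and -1.88 on the arrays). Proteasome mRNAs were higher, with a shift of 0.36 ± 0.54 and 24 of 33 members above 0, and PRE9, a core particle subunit, at 1.54 ± 0.32 and RPT4, an ATPase of the regulatory particle, at 1.30 ± 0.31. No single gene passed the threshold.

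With limma, 0 of 6293 genes passed the adjusted threshold for Gbp2, and 663 had an unadjusted p under 0.05 (387 higher, 276 lower), where chance alone would give 314.65. The smallest adjusted p was 0.213. The model gave all arrays 1 spread per gene, although the SD of their ratios ran from 0.34 to 0.78. With arrays scaled to the same spread, 402 genes had an unadjusted p under 0.05, and with array weights 356. The excess over chance therefore depended in part on that shared spread. The weights were equal within each pair (0.63 for Gbp2, 1.02 for Hrb1 and 1.55 for Npl3). They therefore did not correct for the poor quality of Npl3 replicate 1. With the replicate block, 1 gene passed the adjusted threshold. Without Gbp2 replicate 1 the count was 14 (11 higher, 3 lower), without Gbp2 replicate 2 it was 9 (7 higher, 2 lower), and without Gbp2 replicate 1 and Npl3 replicate 1 together it was 0. Among the 4 ScanArray arrays alone, the count was 0 in each of the 6 comparisons. Highest by moderated statistic were the reading frames YGR115C at 2.22 ± 0.30 (SE) and YGR114C at 2.90 ± 0.40, and RRP14 (YKL082C), a ribosome biogenesis factor, at 1.86 ± 0.30. Lowest besides PMA1 were EFM6 (YNL024C), a methyltransferase of elongation factor eEF1A, at -1.89 ± 0.28 and AIM17 (YHL021C) at -1.81 ± 0.33. The limma adjusted p of these genes ranged from 0.213 to 0.259.

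The transporter list passed at the preset correlation (adjusted p = 5.48e-06) and had adjusted p = 0.967 with an estimated correlation. It held 6 members lower at an unadjusted p under 0.05, 0 past the threshold over all genes and 1 adjusted over the list alone. HXT3, a hexose transporter, stood at 0.62 and CTR1, a copper transporter, at 0.49. The shift was -0.10 on Gbp2 replicate 1 and -0.91 on replicate 2. The call ended without replicate 2, and in the deposited table, where the shift was -0.17. The cell wall list passed with adjusted p = 3.55e-06 (adjusted p = 0.967 with an estimated correlation), with 12 members lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. YPS1, a cell surface protease, stood at -1.39 ± 0.42, and AGA2, a mating agglutinin subunit, at 0.61. Its shift was -0.26 on Gbp2 replicate 1 and -0.68 on replicate 2, and -0.39 with scanner format as a block.

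The proteasome list passed with adjusted p = 0.000278 (adjusted p = 0.967 with an estimated correlation). It had 8 members higher and 1 lower at an unadjusted p under 0.05, 0 over all genes and 3 adjusted over the list alone. Its shift was -0.02 on Gbp2 replicate 1 and 0.74 on replicate 2, and the call ended without replicate 2 and among genes above background on every array, at 0.43. Mitochondrial ribosomal protein mRNAs were higher, with a shift of 0.19 ± 0.33 (adjusted p = 0.0131, and adjusted p = 0.982 with an estimated correlation). Of its 70 members 48 were above 0, 8 of them at an unadjusted p under 0.05, with 0 over all genes and 0 adjusted over the list alone. MRPL50 stood at 1.67, from 2.98 and 0.36 on the arrays, and MRPS16 at 1.28. Without Gbp2 replicate 2 the shift was -0.04 and among genes above background on every array 0.10, and either ended the call. With scanner format as a block it was 0.26.

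Ribosome biogenesis mRNAs were higher with Gbp2 by 0.26 ± 0.75 (adjusted p = 0.0316, and adjusted p = 0.982 with an estimated correlation). Of 94 members 65 were above 0. At an unadjusted p under 0.05, 11 were higher and 3 lower, with 0 over all genes and 2 adjusted over the list alone. NOP56, a core protein of box C/D snoRNPs, stood at 2.08 ± 0.55 and the helicase gene DBP6 at -0.89 ± 0.30. The arrays differed in direction, with 0.79 on Gbp2 replicate 1 and -0.26 on replicate 2. The call ended without replicate 1, with median centring (0.17), without background correction (0.25) and with scanner format as a block (0.06). The last value is an extrapolation, since both Gbp2 arrays were read with ScanArray. On Gbp2 replicate 1 the Arabidopsis control spots had a median brightness of 6671.5 in the lysate channel, against 365.5 for buffer spots.

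Ergosterol biosynthesis mRNAs were lower with Gbp2 by -0.34 ± 0.21 (adjusted p = 0.0102, and adjusted p = 0.982 with an estimated correlation), with 17 of 24 members below 0, 7 of them at an unadjusted p under 0.05, 0 over all genes and 2 adjusted over the list alone. ERG13, the HMG-CoA synthase, stood at -1.71 ± 0.39 and ERG11 at 0.48. The call ended without Gbp2 replicate 1, at -0.19, with scanner format as a block, at -0.10, and among genes above background on every array, at -0.43. Amino acid biosynthesis mRNAs were lower by -0.16 ± 0.17 (adjusted p = 0.0383, and adjusted p = 0.982 with an estimated correlation), with 45 of 69 members below 0. ILV1, the threonine deaminase, stood at -1.23 and ARG3 at 0.84. Among these members 2 were higher and 6 lower at an unadjusted p under 0.05, with 0 over all genes and 0 adjusted over the list alone. The call ended without Gbp2 replicate 1 (-0.04), without Npl3 replicate 1 (at an unaltered shift of -0.16), with median centring (-0.23), without background correction (-0.16), among genes above background on every array (-0.25) and with scanner format as a block (-0.10).

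For Hrb1, camera at the preset correlation placed ribosome biogenesis mRNAs higher and those of the cell wall and of sugar metabolism lower. None passed with an estimated correlation (adjusted p = 0.967, 0.967 and 0.982 with an estimated correlation). Ribosome biogenesis mRNAs were higher by 0.65 ± 0.56 (SD, n = 2), with 82 of 94 members above 0. RRP14 stood at 1.73 ± 0.30 (SE) and CBF5, the pseudouridine synthase of box H/ACA snoRNPs, at 1.49 ± 0.28. ESF1, a nucleolar factor of rRNA processing that the list did not include, stood at 1.92 ± 0.35. Cell wall mRNAs were lower by -0.79 ± 0.28, with 39 of 41 members below 0, among them the mannoprotein mRNAs CWP2 at -2.41 ± 0.34 and SED1 at -2.52 ± 0.38. Glycolysis and fermentation mRNAs were lower by -0.88 ± 0.75, with 21 of 21 members below 0 in the mean of the arrays. The shift was -0.35 on replicate 2, and the call ended without replicate 1.

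With limma, 0 of 6293 genes passed the adjusted threshold for Hrb1, and 483 had an unadjusted p under 0.05 (203 higher, 280 lower), where chance alone would give 314.65. The smallest adjusted p was 0.375. At the ends of the ranking stood RRP14, ESF1, CBF5, CWP2, SED1 and SDS22 (YKL193C), a regulator of protein phosphatase 1, at -1.85 ± 0.29, with adjusted p between 0.375 and 0.423.

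The ribosome biogenesis list passed with adjusted p = 9.00e-16 at the preset correlation and had adjusted p = 0.967 with an estimated correlation. At an unadjusted p under 0.05, 27 members were higher and 1 lower, with 0 over all genes and 2 adjusted over the list alone. NOP7, a factor of the large ribosomal subunit, stood at 1.66, from 2.76 and 0.55 on the arrays, and IMP3, of the small subunit processome, at -1.19. The shift was 1.05 on Hrb1 replicate 1, read with ScanArray, and 0.25 on replicate 2, read with the Agilent scanner. In the deposited table it was 0.26, and the call ended. The cell wall list passed with adjusted p = 3.73e-15 (adjusted p = 0.967 with an estimated correlation). It had 18 members lower at an unadjusted p under 0.05, 0 over all genes and 15 adjusted over the list alone. Its shift was -0.99 on Hrb1 replicate 1 and -0.60 on replicate 2. SCW11, a glucanase of daughter cell separation, stood at 0.41 and FLO11 at 0.25.

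The glycolysis list passed with adjusted p = 1.17e-05 (adjusted p = 0.982 with an estimated correlation), with 0 members at an unadjusted p under 0.05 and 0 adjusted over the list alone. The glucokinase mRNA GLK1 had the lowest mean, -1.36, from -2.99 and 0.26 on the arrays, and the alcohol dehydrogenase mRNA ADH1 stood at -0.18. Its shift was -1.41 on Hrb1 replicate 1 and -0.35 on replicate 2, and the call ended without replicate 1. Chaperone and heat shock mRNAs were lower by -0.46 ± 0.53 (adjusted p = 0.00348, and adjusted p = 0.982 with an estimated correlation), with 26 of 36 members below 0, 7 of them at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. HSP26, a small heat shock protein mRNA, stood at -2.35 ± 0.63, from -3.96 and -0.74, and SSZ1 at 0.50. The shift was -0.84 on Hrb1 replicate 1 and -0.09 on replicate 2, and the call ended without replicate 1, in the deposited table, at -0.26, and among genes above background on every array, at -0.57.

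Respiratory chain and ATP synthase mRNAs were lower with Hrb1 by -0.34 ± 0.21 (adjusted p = 1.27e-05, and adjusted p = 0.967 with an estimated correlation), with 32 of 39 members below 0, 10 of them at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. CYC7, a cytochrome c isoform mRNA, stood at -1.64 and NDE1, an external NADH dehydrogenase mRNA, at 1.34. The shift was -0.49 on Hrb1 replicate 1 and -0.20 on replicate 2, and the call ended in the deposited table, at -0.21. Ergosterol mRNAs were lower by -0.38 ± 0.57 (adjusted p = 0.0047, and adjusted p = 0.982 with an estimated correlation), with 19 of 24 members below 0. At an unadjusted p under 0.05, 1 was higher and 6 were lower, with 0 over all genes and 2 adjusted over the list alone. ERG28 stood at -2.06 and ERG7, the lanosterol synthase, at 1.05. The shift was -0.79 on Hrb1 replicate 1 and 0.02 on replicate 2, and the call ended without replicate 1, in the deposited table, at -0.23, and among genes above background on every array, at -0.17.

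For Npl3, camera at the preset correlation placed mRNAs of the cell wall, of sugar metabolism and of chaperones lower, on arrays of unequal quality. None passed with an estimated correlation (adjusted p = 0.967, 0.982 and 0.982 with an estimated correlation), and the last 2 calls ended without Npl3 replicate 1. Cell wall mRNAs were lower by -0.34 ± 0.06 (SD, n = 2), with 35 of 41 members below 0, among them SED1 at -1.66 ± 0.38 (SE), PIR3 at -1.24 ± 0.30 and AGA1, the anchor of the mating agglutinin, at -1.41 ± 0.34. Glycolysis mRNAs were lower by -0.38 ± 0.36, with 16 of 21 members below 0, and the pyruvate kinase mRNA CDC19 at -1.38. Chaperone mRNAs were lower by -0.24 ± 0.01, with 26 of 36 members below 0. On Npl3 replicate 1 only 11.5% of spots were found and duplicate spots correlated at r = 0.194.

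With limma, 0 of 6293 genes passed the adjusted threshold for Npl3, and 87 had an unadjusted p under 0.05 (44 higher, 43 lower), fewer than the 314.65 that chance would give. The smallest adjusted p was 1.00. With arrays scaled to the same spread, 347 genes had an unadjusted p under 0.05, and with array weights 254. The low number therefore depended on the spread shared by all arrays. Highest in the main setting were the reading frames YLR162W at 1.96 ± 0.48 and, both related to Ty retrotransposons, YBL101W-A at 1.95 ± 0.37 and YAR010C at 1.57 ± 0.39. SED1, PIR3 and AGA1 were lowest. These 6 genes had an adjusted p of 1.00.

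The cell wall list passed with adjusted p = 2.19e-10 (adjusted p = 0.967 with an estimated correlation), with 8 members lower at an unadjusted p under 0.05, 0 over all genes and 3 adjusted over the list alone. HSP150, a secreted mannoprotein mRNA, stood at -1.73, from -2.49 and -0.98, and FLO9 at 0.44. Its shift was -0.30 on Npl3 replicate 1 and -0.38 on replicate 2, and -0.22 in the deposited table, where the call ended. The glycolysis list passed with adjusted p = 0.00174 (adjusted p = 0.982 with an estimated correlation), with 1 member lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. CDC19 gave -2.42 on Npl3 replicate 1 and -0.34 on replicate 2, and the list -0.64 and -0.13. The call ended without Npl3 replicate 1 and without background correction, at -0.13. The chaperone list passed with adjusted p = 0.00348 (adjusted p = 0.982 with an estimated correlation), with 2 members lower at an unadjusted p under 0.05, 0 over all genes and 0 adjusted over the list alone. The call ended without Npl3 replicate 1, at -0.24, without background correction, at -0.13, and in the deposited table, at -0.14.

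Respiratory chain mRNAs gave -0.18 ± 0.02 for Npl3 (adjusted p = 0.0268, and adjusted p = 0.967 with an estimated correlation), with 26 of 39 members below 0 and ATP1 at -1.03. Without replicate 1 the shift was -0.17 and without replicate 2 it was -0.19, and either ended the call. Amino acid biosynthesis mRNAs gave -0.11 ± 0.02 (adjusted p = 0.0316, and adjusted p = 0.982 with an estimated correlation), with 45 of 69 members below 0, ILV5 at -1.14 and GDH1 at 1.15. Without replicate 1 the shift was -0.09 and without replicate 2 it was -0.12, and either ended the call. Ergosterol mRNAs gave -0.16 ± 0.11 (adjusted p = 0.0153, and adjusted p = 0.982 with an estimated correlation), with 19 of 24 members below 0 and ERG6 at -1.14. Without replicate 1 the shift was -0.08 and without replicate 2 it was -0.24, and either ended the call. In the deposited table the 3 calls ended, at -0.04, -0.17 and -0.18 in the same order. The respiratory call also ended with median centring, at -0.11, and the ergosterol call without background correction, at -0.05. Among genes above background on every array the amino acid and ergosterol calls ended, at -0.31 and -0.26. In these lists 0 genes passed over all genes and 0 adjusted over the list alone, and 0, 2 and 1 members were lower at an unadjusted p under 0.05.

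Intron-containing genes, the transcripts the series title is about, did not pass the camera test against intronless genes in any eluate. Their shift was 0.04 ± 0.20 (SD, n = 2) for Gbp2, -0.01 ± 0.25 for Hrb1 and 0.06 ± 0.02 for Npl3, with 117, 107 and 124 of 217 members above 0. Among single transcripts, RPS6A, a small-subunit ribosomal protein gene, stood at 1.48 ± 0.53 (SE) for Gbp2, 1.03 ± 0.53 for Hrb1 and 0.52 ± 0.53 for Npl3. On the arrays it gave 2.35 and 0.61 for Gbp2, 1.95 and 0.10 for Hrb1 and 0.86 and 0.18 for Npl3. ACT1, the actin gene, stood at -0.67 ± 0.34, -0.63 ± 0.34 and -0.86 ± 0.34, and below 0 on the 5 arrays where it was above background in both channels. DBP2, an RNA helicase gene, gave 0.09 ± 0.65 (from 1.30 and -1.12 on the arrays), 1.32 ± 0.65 (from 2.44 and 0.19) and 0.48 ± 0.65, and YRA1, an mRNA export adaptor gene, 0.33 ± 0.30, -0.00 ± 0.30 and -0.02 ± 0.30.

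The limma adjusted p of the intron-containing list was 0.602 for Gbp2, 0.950 for Hrb1 and 0.450 for Npl3, and 0.982, 0.995 and 0.982 with an estimated correlation. At an unadjusted p under 0.05, 10 members were higher and 7 lower for Gbp2, 3 and 11 for Hrb1 and 1 and 1 for Npl3, with 0 over all genes and 0 adjusted over the list alone. The differences were -0.02 for Gbp2 against Npl3 (adjusted p = 0.998), -0.06 for Hrb1 against Npl3 (adjusted p = 0.540) and 0.04 for Gbp2 against Hrb1 (adjusted p = 0.567). For Hrb1 the median shift was -0.01 and the mean 0.01, and for Gbp2 against Npl3 the median was -0.02 and the mean 0.00044, with the test on the side of the median in both. With median centring in place of loess the shift was -0.09 for Npl3, 0.18 for Gbp2 against Npl3 and 0.08 for Hrb1 against Npl3, each of the opposite sign.

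On single arrays the intron-containing list went in either direction. It gave 0.17 and -0.10 on the Gbp2 arrays, 0.17 and -0.18 on the Hrb1 arrays and 0.07 and 0.04 on the Npl3 arrays, with a mean over 6 arrays of 0.03 (exact sign-flip p = 0.656). Leaving out Gbp2 replicate 2 brought Gbp2 to 0.17 (adjusted p = 0.0243) and Gbp2 against Hrb1 to 0.18 (adjusted p = 0.0243). Leaving out Hrb1 replicate 1 brought Hrb1 to -0.18 (adjusted p = 0.00433), Hrb1 against Npl3 to -0.24 (adjusted p = 0.000333) and Gbp2 against Hrb1 to 0.22 (adjusted p = 0.00621). Over all alternatives the adjusted p ran from 0.0243 to 0.960 for Gbp2, from 0.00433 to 0.996 for Hrb1, from 0.000333 to 0.846 for Hrb1 against Npl3 and from 0.00621 to 0.781 for Gbp2 against Hrb1. Leaving out Gbp2 replicate 1 gave -0.10 for Gbp2 and -0.10 for Gbp2 against Hrb1. Leaving out Hrb1 replicate 2 gave 0.17 for Hrb1, 0.11 for Hrb1 against Npl3 and -0.13 for Gbp2 against Hrb1, and leaving out Gbp2 replicate 2 gave 0.12 for Gbp2 against Npl3. Within ScanArray, Hrb1 against Npl3 was 0.10, Gbp2 against Npl3 -0.04 and Gbp2 against Hrb1 -0.13, and within Agilent Hrb1 against Npl3 was -0.22. With scanner format as a block, the values were -0.06 for Gbp2 and -0.05 for Gbp2 against Hrb1.

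**Figure D2:**
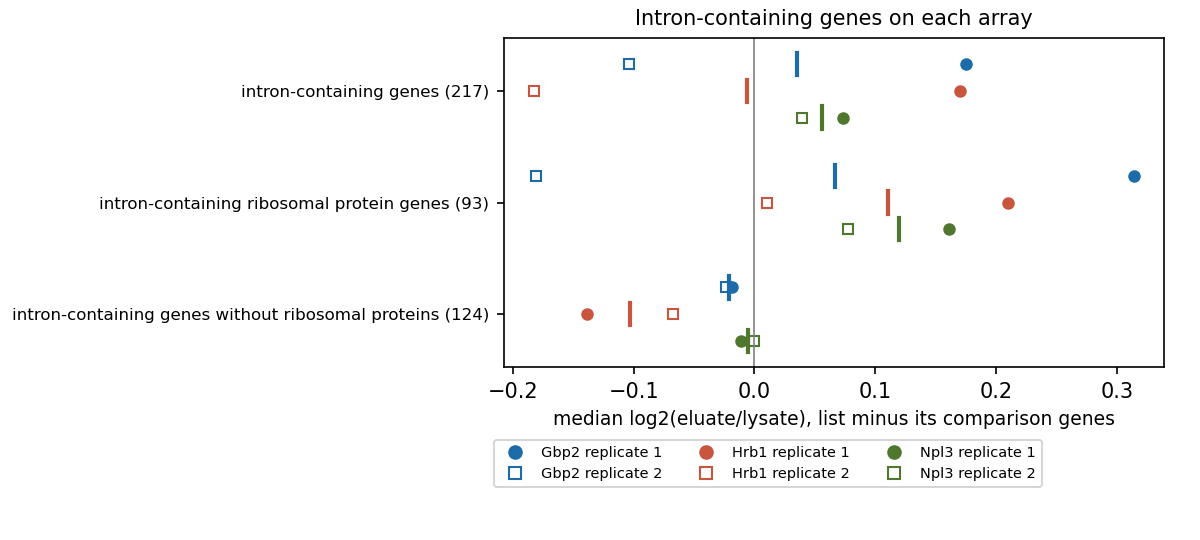
Median log2(eluate/lysate) of the intron-containing genes and of their subsets minus that of their comparison genes, per array. Filled circles are replicate 1, open squares replicate 2 and short bars the mean of the pair, and the full list gives 0.17 and -0.18 on the Hrb1 arrays. With median centring in place of loess the Npl3 value of the full list was -0.09.

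Ribosomal protein genes make up much of the spliced mRNA of yeast, so the list was divided. The 93 intron-containing ribosomal protein genes, set against the intronless ribosomal protein genes, shifted by 0.07 for Gbp2, 0.11 for Hrb1 and 0.12 for Npl3 (adjusted p = 0.854, 0.477 and 0.410). For Gbp2 the mean was -0.02, and the test took that sign. The 124 other intron-containing genes gave -0.02, -0.10 and -0.01 (adjusted p = 0.968, 0.355 and 0.854), with means of 0.02 for Gbp2 and Npl3 on the side the test took. Their shift was below 0 on 6 of 6 arrays, but only by -5.41e-05 on Npl3 replicate 2 (exact sign-flip p = 0.0313, the smallest possible, and 0.208 adjusted over 20 lists). The 43 intronless ribosomal protein genes gave 0.14, 0.07 and -0.00 (adjusted p = 0.329, 0.968 and 0.910), with means of 0.01 for Hrb1, where the test was on the lower side, and 0.03 for Npl3. Highest among intron-containing genes were RPS6A for Gbp2, DBP2 for Hrb1 and RPL23B for Npl3 (1.46, from 2.60 and 0.32 on the arrays). Lowest were RPL39 for Gbp2 at -1.12 and RPS27B for Hrb1 at -1.53.

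For Gbp2 against Npl3, camera at the preset correlation placed proteasome and chaperone mRNAs higher and plasma membrane transporter mRNAs lower. None passed with an estimated correlation (adjusted p = 0.967, 0.982 and 0.967 with an estimated correlation), and all 3 calls ended without Gbp2 replicate 2. Proteasome mRNAs differed by 0.47, with 28 of 33 members higher and PRE6 at 1.42 and PRE9 at 1.30. Chaperone mRNAs differed by 0.40, with 26 of 36 members higher, among them the J-protein mRNA SIS1 at 1.76 and the Hsp70 mRNA SSA2 at 1.44. Transporter mRNAs differed by -0.41, with 32 of 43 members lower and PMA1 at -1.85 ± 0.46 (SE).

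With limma, 0 of 6293 genes passed for Gbp2 against Npl3, and 203 had an unadjusted p under 0.05 (127 higher, 76 lower), fewer than the 314.65 of chance. The genes at the ends were SEC2, an exchange factor of secretory vesicles, at 2.22 ± 0.48, TOS4 at 1.84 ± 0.40, YGR114C at 2.34 ± 0.57, EFM6 at -1.95 ± 0.39, MAK31 at -1.85 ± 0.44 and PMA1, with an adjusted p of 0.993. The proteasome list passed with adjusted p = 1.17e-05 (adjusted p = 0.967 with an estimated correlation), the transporter list with adjusted p = 0.000482 (adjusted p = 0.967 with an estimated correlation) and the chaperone list with adjusted p = 0.0131 (adjusted p = 0.982 with an estimated correlation). Within these lists 4, 3 and 2 members passed an unadjusted p under 0.05 in the list's direction, with 0 over all genes and 0 adjusted over the list alone. Without Gbp2 replicate 2 the differences were 0.09 for the proteasome, -0.00 for transporters and 0.05 for chaperones, and each call ended, and the chaperone call also ended without Npl3 replicate 1, at 0.40, and without background correction, at 0.28. In the deposited table all 3 calls ended, at 0.32, -0.08 and 0.16, and the transporter call also ended among genes above background on every array, at -0.41. Without Gbp2 replicate 1 they were 0.85, -0.82 and 0.75. Within ScanArray, where Npl3 had replicate 1 alone, the differences were 0.41, -0.40 and 0.40, and with scanner format as a block 0.46, -0.41 and 0.59.

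For Hrb1 against Npl3, camera at the preset correlation placed ribosome biogenesis mRNAs higher and cell wall mRNAs lower. Neither passed with an estimated correlation (adjusted p = 0.982 and 0.967 with an estimated correlation), and both calls ended without Hrb1 replicate 1. Ribosome biogenesis mRNAs differed by 0.58, with 80 of 94 members higher, among them the large subunit factors SSF1 at 1.64 and BRX1 at 1.49. Cell wall mRNAs differed by -0.45, with 33 of 41 members lower and the cold shock mannoprotein mRNA TIR1 at -2.01. Respiratory chain mRNAs differed by -0.16, with 28 of 39 lower and CYC7 at -1.75, and translation factor mRNAs by 0.17, with 27 of 40 higher and GCD11, a subunit of initiation factor eIF2, at 0.97. Transcripts of SR-like, export and surveillance proteins differed by 0.17, with 29 of 37 higher, PAB1, the poly(A) binding protein gene, at 0.82 and RRP6, a nuclear exosome gene, at -0.77.

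With limma, 0 of 6293 genes passed for Hrb1 against Npl3, and 101 had an unadjusted p under 0.05 (27 higher, 74 lower), fewer than the 314.65 of chance. The genes at the ends were ESF1 at 1.79 ± 0.49 (SE), YDL152W at 1.42 ± 0.40, RRP14 at 1.32 ± 0.42, SDS22 at -1.80 ± 0.42, SLD2, a replication factor, at -2.19 ± 0.52 and YJL188C at -1.91 ± 0.48, with an adjusted p of 1.00. The ribosome biogenesis list passed with adjusted p = 9.34e-13 (adjusted p = 0.982 with an estimated correlation). The lists of the cell wall, the respiratory chain, translation factors and SR-like proteins passed with adjusted p = 0.000423, 0.0131, 0.0465 and 0.0383, and all had adjusted p = 0.967 with an estimated correlation. At an unadjusted p under 0.05, 4 ribosome biogenesis members were higher, 5 cell wall and 3 respiratory members lower, and 0 members of the other lists passed, with 0 over all genes and 0 adjusted over the list alone.

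These differences were larger within ScanArray than within Agilent. They were 0.97 and 0.19 for ribosome biogenesis, -0.69 and -0.22 for the cell wall, -0.29 and -0.03 for the respiratory chain, 0.28 and 0.06 for translation factors and 0.33 and 0.01 for SR-like proteins. Each value sets 1 array against 1. The ScanArray array of Npl3 was replicate 1, where 11.5% of spots were found, so the scanner cannot be told apart from array quality. Scanner format as a block cannot alter these differences, since each of the 2 proteins has 1 array per scanner, but it alters the spread, and the calls for translation factors and SR-like proteins ended with it. Without Hrb1 replicate 1 all 5 calls ended, at 0.18, -0.26, -0.02, 0.03 and 0.09 in the same order, and without Hrb1 replicate 2 the values were 0.98, -0.65, -0.31, 0.31 and 0.26. The cell wall difference was -0.26 with arrays scaled to the same spread, -0.35 with median centring and -0.18 among genes above background on every array, and the respiratory one -0.06 with scaling, and each call ended. The respiratory call also ended without Npl3 replicate 2 (-0.15) and in the deposited table (-0.17). The call for SR-like proteins ended without Npl3 replicate 1 (0.09) and without Hrb1 replicate 2, and that for translation factors without Npl3 replicate 1 (0.20), Npl3 replicate 2 (0.14) or Gbp2 replicate 2 (0.17). The calls for translation factors and SR-like proteins stayed in only 3 of 8 settings. They also ended without background correction (0.13 and 0.09), in the deposited table (0.05 and 0.13) and among genes above background on every array (0.23 and 0.21).

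For Gbp2 against Hrb1, the 2 related proteins, camera at the preset correlation placed mRNAs of chaperones, the cell wall, the respiratory chain and the proteasome higher, and those of transporters and ribosome biogenesis lower. None passed with an estimated correlation (adjusted p = 0.982, 0.982, 0.967, 0.967, 0.967 and 0.982 with an estimated correlation). With 1 array left out, the proteasome and ribosome biogenesis differences changed sign. Chaperone mRNAs differed by 0.62, with 27 of 36 members higher and the heat shock protein mRNAs HSP42 at 3.04 ± 1.05 (SE), or 1.22 without Hrb1 replicate 1, where it stood at -3.64, and HSP12 at 2.44, from -4.06 and -0.57 on the Hrb1 arrays. Transporter mRNAs differed by -0.60, with 33 of 43 lower and PMA1 at -2.15 ± 0.46. Ribosome biogenesis mRNAs differed by -0.38, with 75 of 94 lower and NSR1, a nucleolar protein gene, at -1.54, but by 0.10 in the deposited table, where the chaperone and respiratory calls ended too, at 0.27 and 0.07. Cell wall mRNAs differed by 0.32, with 26 of 41 higher and TIR3 at 2.40, respiratory chain mRNAs by 0.28, with 29 of 39 higher, and proteasome mRNAs by 0.26, with 25 of 33 higher and RPN12 at 1.45.

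With limma, 0 of 6293 genes passed for Gbp2 against Hrb1, and 352 had an unadjusted p under 0.05 (224 higher, 128 lower), where chance would give 314.65. With arrays scaled to the same spread this number was 251, and with array weights 231. The genes at the ends were SLD2 at 2.53 ± 0.52, YDR543C at 2.16 ± 0.47, CWP2 at 2.20 ± 0.48, EFM6 at -2.06 ± 0.39, AUR1, a sphingolipid synthase gene, at -1.74 ± 0.36 and PMA1, with an adjusted p of 0.833. The lists of transporters, the proteasome and the respiratory chain passed with adjusted p = 1.17e-05, 0.0131 and 0.0131, and each had adjusted p = 0.967 with an estimated correlation. The lists of ribosome biogenesis, chaperones and the cell wall passed with adjusted p = 4.42e-05, 0.00348 and 0.0383, and each had adjusted p = 0.982 with an estimated correlation. At an unadjusted p under 0.05, 5 transporter and 6 ribosome biogenesis members were lower, and 6 chaperone, 6 cell wall, 2 respiratory and 1 proteasome members higher, with 0 over all genes and 0 adjusted over the list alone.

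Each of these 6 calls ended when 1 or another array was left out. Without Gbp2 replicate 2 the calls ended for transporters (-0.20), ribosome biogenesis (0.15), chaperones (0.27), the respiratory chain (0.17) and the proteasome (-0.12). Without Hrb1 replicate 1 they ended for ribosome biogenesis (0.02), chaperones (0.25), the cell wall (0.12) and the respiratory chain (0.13), without Gbp2 replicate 1 for the cell wall (0.11), and without Hrb1 replicate 2 for the proteasome (0.30). Without Gbp2 replicate 1 and Npl3 replicate 1 together they ended for the cell wall (0.11) and the respiratory chain (0.39). Within ScanArray the differences were 0.99 for chaperones, -0.61 for transporters, -0.78 for ribosome biogenesis, 0.52 for the cell wall, 0.43 for the respiratory chain and 0.30 for the proteasome. With scanner format as a block they were 0.81, -0.60, -0.59, 0.40, 0.36 and 0.25. Without Gbp2 replicate 1 they were 0.97 for chaperones, -1.01 for transporters, -0.91 for ribosome biogenesis and 0.65 for the proteasome. Among genes above background on every array the calls ended for ribosome biogenesis (-0.07), the proteasome (0.48), the cell wall (0.19) and transporters (-0.74). Without Hrb1 replicate 2 the differences equalled the ScanArray values, and without Gbp2 replicate 2 the cell wall difference was 0.53.

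Replicates of a protein were not the closest pairs of arrays. The Gbp2 and Npl3 pairs correlated less than most pairs of different proteins did, and the Hrb1 pair more than most of them. Across genes, which are not independent replicates, the log2 ratios correlated at Pearson r = 0.02 between the Gbp2 arrays, 0.26 between the Hrb1 arrays and 0.04 between the Npl3 arrays. The highest of the 15 correlations was 0.59, between Hrb1 replicate 2 and Npl3 replicate 2, which were read on the same scanner and day. Gbp2 replicate 1 and Hrb1 replicate 1 gave 0.33, and Gbp2 replicate 2 and Npl3 replicate 2 gave 0.30.

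**Figure D3:**
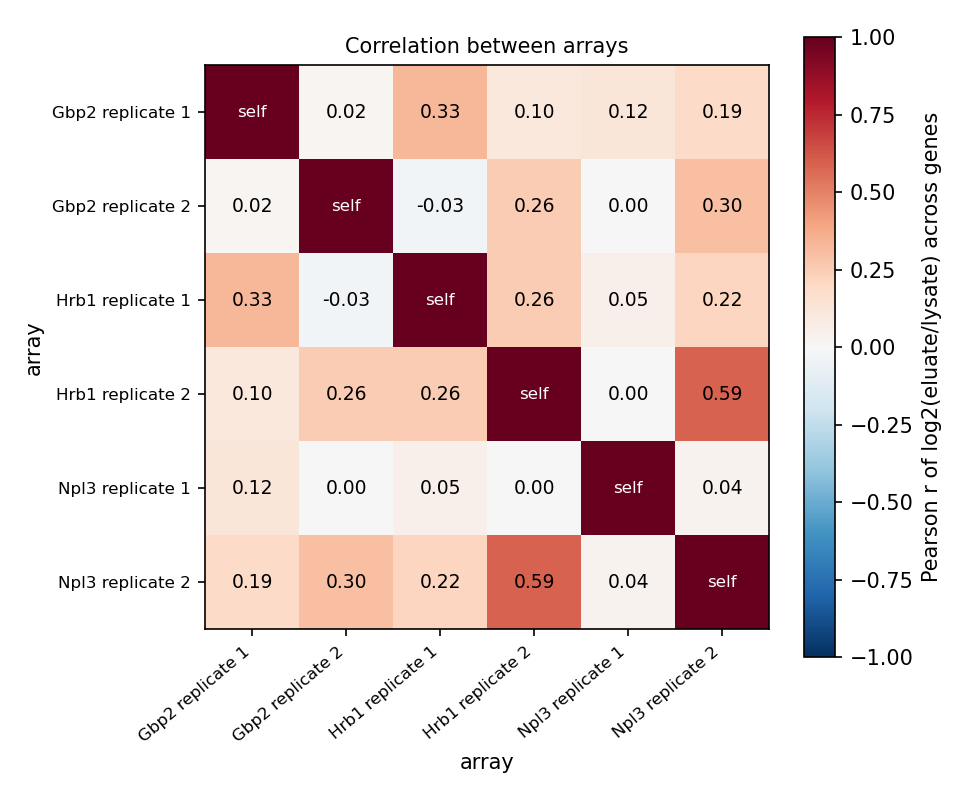
Pearson correlation across genes of the log2(eluate/lysate) values for each pair of the 6 arrays, as a heat map with the value written in each field. The pair Hrb1 replicate 2 and Npl3 replicate 2 stands at 0.59, and the replicate pairs at 0.02, 0.26 and 0.04.

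The transcripts of the tagged proteins themselves gave mixed values. GBP2 mRNA stood at 0.11 ± 0.39 (SE) with Gbp2 (from -0.45 and 0.66 on the arrays), 0.81 ± 0.39 with Hrb1 (from 1.42 and 0.20) and 0.07 ± 0.39 with Npl3. HRB1 mRNA stood at 0.03 ± 0.30, -0.21 ± 0.30 and -0.00 ± 0.30. NPL3 mRNA stood at 0.94 ± 0.41, 0.56 ± 0.41 and 0.51 ± 0.41 and above 0 on 6 of 6 arrays, from 0.12 to 1.75. None of the transcripts GBP2, HRB1 and NPL3 was above background in both channels on Npl3 replicate 1.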

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

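The tests of a lysate RNA pool over all 3 gene groups and of a dye bias following brightness over all 6 arrays were planned before their results were seen, and the other explanation tests below were chosen only after the result was seen. All of the list differences named first passed the camera test of the difference itself at the preset correlation, and none did with an estimated correlation. No biological explanation was tested, since the design offers the bound protein alone, and that stays open.

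Differences between proteins drew attention in these groups. Ribosome biogenesis mRNAs differed by 0.58 for Hrb1 against Npl3 and by -0.38 for Gbp2 against Hrb1. Translation factor mRNAs differed by 0.17 for Hrb1 against Npl3. Proteasome mRNAs differed by 0.47 for Gbp2 against Npl3 and by 0.26 for Gbp2 against Hrb1, and chaperone mRNAs by 0.40 and 0.62. Cell wall mRNAs differed by -0.45 for Hrb1 against Npl3 and by 0.32 for Gbp2 against Hrb1. Transporter mRNAs differed by -0.41 for Gbp2 against Npl3 and by -0.60 for Gbp2 against Hrb1. Respiratory chain mRNAs differed by -0.16 for Hrb1 against Npl3 and by 0.28 for Gbp2 against Hrb1. Transcripts of SR-like, export and surveillance proteins differed by 0.17 for Hrb1 against Npl3.

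A signal outside the gene spots stood out on Gbp2 replicate 1. Its Arabidopsis control spots had a median brightness of 6671.5 in the lysate channel and 2165 in the eluate channel, against 365.5 and 127 for its buffer spots, whereas on the other arrays the lysate medians of the Arabidopsis and buffer spots lay close together (112 and 108 on Gbp2 replicate 2).

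The cell wall list was lower in the eluate on 6 of 6 arrays. A dye bias that follows spot brightness was argued against as the whole cause, because without loess the list lay at percentile 0.24 or lower among 10000 lists matched on brightness on 5 of 6 arrays, but on Npl3 replicate 1, where few spots were found, it lay at percentile 39.21 and such a bias may account for the value. Eluates poor in all mRNAs translated at the endoplasmic reticulum cannot be told apart from a loss of cell wall mRNAs alone, since the transporter list, which also encodes membrane-targeted proteins, was below 0 on 4 arrays and above 0 on the Hrb1 arrays (0.10 and 0.09), where its gap to the cell wall list was 0.96 SDs of the transporter members on replicate 1 and 2.11 on replicate 2, so beyond their spread on 1 array only. A dye effect of these genes common to all arrays cannot be told apart from binding, since 0 arrays had the opposite orientation of the dyes. Such an effect would cancel from the differences between proteins only if it had the same size on all arrays, whose ratios had unequal spread. The cell wall differences passed camera for Hrb1 against Npl3 and Gbp2 against Hrb1 at the preset correlation. Neither passed with an estimated one (adjusted p = 0.967 and adjusted p = 0.982 with an estimated correlation). Both calls ended without Hrb1 replicate 1 and the former with arrays scaled to the same spread, so a real difference in binding stays open as untested.

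The Gbp2 arrays gave opposite shifts for glycolysis (-1.10 and 0.61), cytosolic ribosomal protein (0.56 and -0.17) and ribosome biogenesis mRNAs (0.79 and -0.26). Gbp2 replicate 2 was the only array above 0 for glycolysis and the only array below 0 for ribosome biogenesis. For ribosomal protein genes Hrb1 replicate 2 was below 0 too (-0.28). Hrb1 replicate 1 went the way of Gbp2 replicate 1, at -1.41, 0.54 and 1.05. Displaced names and a different lysate pool were tested for Gbp2 replicate 1 only, so the same faults on replicate 2 stay untested. Displaced spot names over the whole of Gbp2 replicate 1 were argued against, since the 3 groups lay at a largest tail percentile of 0 among 10000 random lists. A different lysate RNA pool on Gbp2 replicate 1 gave no single answer over the 3 groups. The share of the difference in the lysate channel was -2.44% for ribosome biogenesis, 34.4% for glycolysis and 314% for ribosomal protein genes. Channel brightness was taken after background correction but before loess, so the shares do not divide the loess shifts given above. The first 2 groups were set apart only after these shares were seen, so their low shares cannot exclude such a pool. For ribosome biogenesis the arrays differed by 0.02 in the lysate and 0.76 in the eluate, and for glycolysis by 0.73 and -1.39. For ribosomal protein genes they differed by -2.00 and -1.36, so both channels moved and the pool cannot be told apart from an effect on both. An exchange of the dyes on 1 array cannot be told apart from a difference between the Gbp2 experiments in the bound RNA, which stays untested: the correlations were 0.10 and 0.26 with Hrb1 replicate 2 and 0.19 and 0.30 with Npl3 replicate 2, but 0.33 and -0.029 with Hrb1 replicate 1, and a dye effect common to all arrays would make such values positive in either orientation.

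Hrb1 replicate 2 and Npl3 replicate 2 correlated at r = 0.59, more than any replicate pair. Spot noise was argued against as the reason for the lower values of pairs without Npl3 replicate 1, because the duplicate spots of the arrays in them correlated at 0.873 or more. Duplicate spots are adjacent on the same array and share its labelled RNA. Noise of amplification, labelling, hybridisation or slide region, which they have in common, was not tested and stays open. For pairs with Npl3 replicate 1, whose duplicate spots correlated at 0.194, noise may account for the low values. The shared scanner and scan day cannot be told apart from shared biology, because only 1 pair of arrays shared them. RNA bound by both proteins stays open as untested.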

How the results depend on the processing

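The removal of Gbp2 replicate 1 and Npl3 replicate 1 together and the list restricted by span were chosen only after the data were seen, and the other alternatives were planned. Values of named genes moved by less than the replicate spread in 2924 of 3093 cases and by more in 169. Leaving out an array or adding the replicate block cannot move a value beyond that spread. The cases of these settings were therefore fixed in advance and say nothing about stability. Lists past the threshold kept direction and call in 380 of 491 cases, lost the call in 102 and turned in 9. The intron-containing list kept both in 81 of 114 cases, turned in 28 and passed the threshold in 5. Some of these list cases were also fixed in part. Leaving out an array of a protein outside the comparison, or adding the replicate block, cannot alter a list's shift. Neither can scanner format as a block in comparisons without Gbp2. In such cases only the call could change. Taking the mean leaves the camera test as it was, so there only the sign could change. The totals therefore overstate stability. Counts of genes were within 1.5 times in 98 of 102 cases and counts of lists in 71 of 90. The respiratory chain list had too few members above background on every array to give a value there. Where no reason follows from the alternative itself, such as fewer genes or arrays, the cause was not tested. Signal over background limited Npl3 replicate 1, and only 956 genes stood above background on every array.

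With median centring in place of loess, the intron-containing list turned to -0.086 for Npl3, 0.18 for Gbp2 against Npl3 and 0.081 for Hrb1 against Npl3, and the lists past the threshold numbered 10 for Npl3 and 5 for Gbp2 against Npl3. Without background correction it turned to 0.023 for Gbp2 against Npl3, and with an offset of 0 to 0.014 for Hrb1. In the deposited table it turned to 0.070 for Hrb1, -0.041 for Npl3, 0.14 for Gbp2 against Npl3 and 0.11 for Hrb1 against Npl3. There, 3 lists passed for Hrb1, 1 for Npl3 and 3 for Gbp2 against Hrb1, ribosome biogenesis turned to 0.10 for Gbp2 against Hrb1, and the Hrb1 arrays correlated at -0.00696. The direction of that table rested on weak evidence for Hrb1 replicate 2 and Npl3 replicate 2, and the other direction was not tried.

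Among genes above background on every array, 2 genes passed for Hrb1 (both lower), and the intron-containing list turned to 0.14 for Hrb1 and 0.12 for Gbp2 against Npl3. The lists past the threshold were 3 for Hrb1, 3 for Npl3, 1 for Hrb1 against Npl3 and 1 for Gbp2 against Hrb1. With arrays scaled to the same spread 3 lists passed for Hrb1 against Npl3. With scanner format as a block the intron-containing list turned to -0.061 for Gbp2 and -0.055 for Gbp2 against Hrb1, and 3 lists passed for Hrb1 against Npl3. The values with Gbp2 rest on the scanner gap of the other proteins. With the replicate block 1 gene passed for Gbp2, and the calls for translation factors and SR-like proteins ended for Hrb1 against Npl3. The labels name nothing that arrays of 1 number share, so the numbers were not taken as pairs. Deviations from the protein means correlated across genes at 0.315 for Gbp2 and Hrb1, 0.113 for Gbp2 and Npl3 and 0.0968 for Hrb1 and Npl3, which leaves a pairing of Gbp2 and Hrb1 open.

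Without Gbp2 replicate 1 and Npl3 replicate 1 together, the intron-containing list turned to -0.10 for Gbp2 and -0.10 for Gbp2 against Hrb1, ribosome biogenesis turned to -0.26 for Gbp2, and 3 lists passed for Npl3 and 7 for Gbp2 against Npl3. Against intronless genes matched on brightness, the intron-containing list turned to 0.055 for Hrb1. By the mean it turned to 0.014 for Hrb1 and 0.00044 for Gbp2 against Npl3, and without ribosomal protein genes to -0.021 for Gbp2 and -0.0056 for Npl3. Restricted to 127 members by span it turned to 0.045 for Hrb1 and -0.021 for Gbp2 against Hrb1.

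With each array left out in turn, the gene count ran from 0 to 14 for Gbp2 (without Gbp2 replicate 1) and stayed 0 in the other 5 comparisons. The intron-containing list ran from -0.10 to 0.17 for Gbp2, -0.18 to 0.17 for Hrb1, 0.04 to 0.07 for Npl3, -0.16 to 0.12 for Gbp2 against Npl3, -0.24 to 0.11 for Hrb1 against Npl3 and -0.13 to 0.22 for Gbp2 against Hrb1. Lists past the threshold numbered 6 to 8, 6 to 9, 2 to 7, 2 to 7, 3 to 9 and 5 to 8 in the same order. Lists that turned ran as follows, the turned value first. Mitochondrial ribosomal proteins ran from -0.040 (without Gbp2 replicate 2) to 0.43 for Gbp2, and the proteasome from -0.022 (without the same array) to 0.74 for Gbp2 and from -0.12 (without the same array) to 0.65 for Gbp2 against Hrb1. Ribosome biogenesis ran from -0.26 (without Gbp2 replicate 1) to 0.79 for Gbp2. For Gbp2 against Hrb1 it gave 0.15 without Gbp2 replicate 2, 0.017 without Hrb1 replicate 1 and -0.91 without Gbp2 replicate 1. Ergosterol biosynthesis ran from 0.021 (without Hrb1 replicate 1) to -0.79 for Hrb1.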

Other observations

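The exact sign-flip tests of the report were chosen after the data were seen, and the list tests given here were planned. Several gene groups of protein synthesis and RNA handling did not pass the camera test of limma in any eluate. Cytosolic ribosomal protein mRNAs shifted by 0.20 ± 0.51 (SD, n = 2) for Gbp2, 0.13 ± 0.58 for Hrb1 and 0.10 ± 0.06 for Npl3 (adjusted p = 0.228, 0.457 and 0.415), with 89, 82 and 80 of 136 members above 0. On the arrays this list gave 0.56 and -0.17 for Gbp2 and 0.54 and -0.28 for Hrb1. Translation factor mRNAs gave -0.12, 0.05 and -0.12 (adjusted p = 0.549, 0.504 and 0.065), with EFB1, the exchange factor of eEF1A, at 1.33 ± 0.36 (SE) for Gbp2 and DED1, an initiation helicase gene, at -1.04. Spliceosome protein mRNAs gave 0.09, 0.04 and 0.06 (adjusted p = 0.485, 0.471 and 0.40). For Gbp2, 3 of its 75 members were higher and 3 lower at an unadjusted p under 0.05, with 0 over all genes and 2 adjusted over the list alone. Among its members, CWC22 stood at 1.27 ± 0.26 and MSL5, the branch point binding protein gene, at -1.38 ± 0.26. Transcripts of SR-like, export and surveillance proteins gave -0.03, 0.07 and -0.10 (adjusted p = 0.966, 0.469 and 0.0697), with the THO subunit mRNA MFT1 at 1.42 and the export receptor mRNA MEX67 at -0.70 for Gbp2. For Gbp2 the median of that list was below 0 and its mean 0.00, with the test on the lower side.

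The 15 mitochondrial genome transcripts gave 0.04, -0.05 and -0.04 for Gbp2, Hrb1 and Npl3 (adjusted p = 0.854, 0.477 and 0.680). COB and COX1 were above background in both channels on 0 of 6 arrays and COX2 and COX3 on 1, so these values say nothing about binding. Histone mRNAs, which lack introns, gave -0.08, -0.08 and 0.09 (adjusted p = 0.655, 0.813 and 0.602), with HTA2 at 0.48 for Gbp2 and 1.19 for Hrb1, the latter from 2.41 and -0.03 on the arrays. Mitochondrial ribosomal protein mRNAs gave 0.02 for Hrb1 and 0.04 for Npl3 (adjusted p = 0.567 and 0.209), proteasome mRNAs 0.10 and -0.11 (adjusted p = 0.477 and 0.352), and transporter mRNAs 0.10 and -0.10 (adjusted p = 0.635 and 0.247). Ribosome biogenesis mRNAs gave 0.07 for Npl3 (adjusted p = 0.355) and amino acid biosynthesis mRNAs -0.18 for Hrb1 (adjusted p = 0.065), a list below 0 on 6 of 6 arrays (exact sign-flip p = 0.0313, the smallest possible, and 0.208 adjusted). For Gbp2, glycolysis mRNAs gave -0.25 (adjusted p = 0.0718), chaperone mRNAs 0.16 (adjusted p = 0.497) and respiratory chain mRNAs -0.06 (adjusted p = 0.472).

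Some values belong to single genes that the naming rule fixed. ASC1, which carries a snoRNA in its intron, stood at 0.04 ± 0.34 (SE) for Gbp2, -0.04 ± 0.34 for Hrb1 and -0.40 ± 0.34 for Npl3. TDH1, a glyceraldehyde phosphate dehydrogenase mRNA, gave opposite signs on the 2 arrays of every protein, with -1.11 and 0.34 for Gbp2, -1.93 and 0.30 for Hrb1 and -2.82 and 0.27 for Npl3, and was not above background in both channels on Npl3 replicate 1. ECM33, a cell wall protein gene with an intron, stood at -0.62 ± 0.43 for Gbp2 and -0.24 ± 0.43 for Hrb1. For Npl3 it gave -0.51 on replicate 2 and was not above background in both channels on replicate 1. RPL23A stood at 0.65 ± 0.54 for Gbp2 and 0.65 ± 0.54 for Hrb1, and RPS11B at 0.61 ± 0.45 and 0.04 ± 0.45, each above 0 on replicate 1 and below 0 on replicate 2 of both proteins. Spots hold whole reading frames, so paralogous mRNAs such as RPL23A and RPL23B may share signal, and both strands of overlapping frames such as YGR114C and YGR115C may contribute to their spots. Neither was tested.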
